A study of Homo sapiens with 8 samples.

How the data were processed

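The values used were gene counts deposited by the authors for 8 poly(A) RNA libraries of MH7A cells, in 1 table with a column per library. Per the labels' protocols, libraries were made with a NEB kit that does not keep strand. Per the submitters' processing notes, reads were aligned with STAR 2.7.0 and counted with featureCounts, whose version is not given in the sources used here. The notes name the builds mm10 and hg19 and do not say which was used for which step. The symbols in the table are human, and no coordinates are given, since the reference at hand is of another human build and was used only for gene biotypes. The table lists only symbols with at least 1 read, 38173 in all. Reads are not split by strand, so a gene and an antisense partner cannot be told apart. Values of HLA, MT1, AKR1C, TRIM16L, histone, LCE and ribosomal protein genes are uncertain, because similar copies may share reads.

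The 8 columns were matched to the samples by the descriptions in the labels and grouped by the sample titles into 4 groups of 2, with 0 columns unassigned: mock, TNF, TNF with Tubuloside B given at the same time, and Tubuloside B. Tubuloside B was used at 60 µM for 24 h. TNF was at 20 ng/mL in the design text, whereas the treatment labels give the amount per microlitre, and the label of the combined group breaks off within the unit. The label of the mock libraries names DMSO, whereas the design text describes mock cells as incubated as normal. Neither difference could be settled from the sources used here.

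Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr, which left 16647, and libraries were scaled by trimmed mean of M-values. The edgeR quasi-likelihood model had 1 coefficient per group over all 8 libraries, with 4 residual and 13.1 prior degrees of freedom and a common biological coefficient of variation of 4.00%. There were 5 contrasts: TNF against mock, TNF + Tub B against TNF, Tub B against mock, TNF + Tub B against Tub B, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. CPM were scaled by the same factors, and log2 CPM used a prior count of 2. Floors of 3 counts ranged from 0.0939 CPM in TNF replicate 1 to 0.213 CPM in TNF + Tub B replicate 2. For named genes with few counts in a group, ratios of summed counts carry 95% counting intervals. List medians are also given with members of 3 or fewer counts over a group at the bound of such an interval nearer to no change. Where the interval included no change, the member was set to a log2 fold change of 0. Intervals and floors cover counting error only. Mitochondrial genes held 3.10% to 3.80% of counts and the 10 most abundant genes 7.02% to 8.66%.

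The samples, comparisons, alternatives, 35 gene lists and rule for naming genes were fixed before the data were examined. The lists held 715 symbols, of which 645 were tested, and 34 lists had at least 3 tested members. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Genes were named by 3 parts of a rule: a fixed panel of 12 genes, the 8 largest changes per direction (6 for the interaction), and up to 4 members of each list that passed camera. Those chosen by size needed at least 5 CPM in the higher group and no overlap in CPM between the groups. Pseudogenes, read-through and antisense names were passed over, among them GBP1P1, RP11-443P15.2 and LUCAT1.

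The alternatives fixed then were DESeq2 size factors, library totals and upper-quartile scaling in edgeR, DESeq2, limma-voom, no filter, a filter of 1 CPM and 30 counts, fits of only the groups compared, a replicate term, an adjusted p of 0.01, a 2-fold minimum, a prior count of 0.5 and leaving out each library. A fit without 1 library leaves 1 in its group, which is then assumed to vary like the others. Thinning every library to the total of the smallest, and using each TNF library in only 1 of the comparisons set side by side, were chosen after seeing the data.

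The steps were tested on simulated counts with 200 changed genes per comparison. For TNF against mock, 40 of 67 genes changed 1.5-fold, 55 of 67 changed 2-fold and 66 of 66 changed 4-fold were called, as were 6 of 16124 unchanged genes. For TNF + Tub B against TNF the numbers were 43 of 67, 58 of 67, 60 of 66 and 8 of 16217. For Tub B against mock they were 39 of 67, 54 of 67, 66 of 66 and 8 of 16191. Of 1000 random lists of unchanged genes, camera gave a p below 0.05 for 9, 22 and 18 in these comparisons. Simulated genes varied independently of each other, so these lists could not show how camera's preset fares with correlated members. A TNF response set to equal size with Tub B gave a slope of 0.912 and 0 interaction calls, and one set to 0.7 gave 0.645 and 351 calls. Differential splicing, variants and alignment were not analysed here. Some genes that the naming rule selects are not reported here.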

Results

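Poly(A) RNA was sequenced from MH7A, an immortalised human line of rheumatoid arthritis synovial cells used as a model of fibroblast-like synoviocytes. Cells were left as mock, stimulated with tumour necrosis factor (TNF), treated with TNF and Tubuloside B together (TNF + Tub B), or treated with Tubuloside B alone (Tub B). Tubuloside B is a phenylethanoid glycoside, and the series concerns its action on phosphorylation of TAK1, the kinase that links the TNF receptor to NF-κB and MAP kinases. Protein phosphorylation was not measured here. Each of the 4 groups held 2 libraries, and 16647 of the 38173 genes in the count table had enough reads to be tested. Gene counts summed to 28035754 and 18041883 in the mock libraries and 31937334 and 19975540 in the TNF libraries. They summed to 16861895 and 14073186 in TNF + Tub B and 20843251 and 18987139 in Tub B. The first principal component, with 55.8% of the variance, separated libraries with TNF from those without, and the second, with 17.9%, put the 4 libraries with Tub B below the other 4. The chi-square per degree of freedom between the libraries of a group was 5.36 in mock and 2.29 to 2.69 in the other groups, and DNA replication genes differed between the mock libraries (median log2 CPM 5.30 and 4.90). The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are given as CPM, counts scaled to library size, with their SD over the 2 libraries, and log2 fold changes are given ± SE. Adjusted p-values of genes come from edgeR with Benjamini-Hochberg adjustment, and those of gene lists from camera over the 34 lists tested.

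To describe the response to TNF alone, TNF libraries were compared with mock libraries. TNF raised chemokines, NF-κB targets, interferon-stimulated genes and antigen presentation genes almost throughout the lists fixed for them. CXCL8, a neutrophil chemokine, rose from 15.5 ± 2.33 to 748 ± 13.5 CPM (SD, n = 2), and CCL2, a monocyte chemokine, rose from 22.2 ± 1.91 to 513 ± 15.8 CPM. IL6 rose from 1.42 ± 0.302 to 30.5 ± 3.33 CPM and ICAM1, which encodes an adhesion molecule for leukocytes, from 13.2 ± 2.43 to 290 ± 4.96 CPM. Transcripts of MAP3K7, the gene for TAK1, stood at 61.7 ± 4.58 CPM in mock and 60.6 ± 0.535 CPM in TNF libraries (log2 fold change −0.02 ± 0.06, adjusted p = 0.853 in edgeR), a difference within the spread between replicates.

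Of the 29 tested cytokines and chemokines, 27 rose, none fell and 2 did not pass (27 adjusted over the list alone). CXCL10 and CXCL11, ligands of CXCR3, a chemokine receptor of T cells, led the list. CXCL10 had 3 and 1 counts in the mock libraries and 175 ± 21.4 CPM with TNF, a ratio of 1969 (95% counting interval 769 to 7228). CXCL11 rose by 7.12 ± 0.21 and CCL5, another T cell chemokine, by 3.95 ± 0.16 on the log2 scale. CSF2, which encodes a granulocyte-macrophage growth factor, had 9 counts over the mock libraries and was 81.8 times higher with TNF (interval 42.9 to 180). The list's median log2 fold change was 3.84, or 3.31 with the 2 members of 3 or fewer mock counts set at their bound. The list stood above other genes in camera (adjusted p = 7.14e-24) and also did so with an estimated correlation (adjusted p = 0.0132). Among 28 tested NF-κB targets and feedback regulators, 27 rose and 1 did not pass (28 adjusted over the list alone). BIRC3, an inhibitor of apoptosis, rose by 6.67 ± 0.10, SOD2, the mitochondrial superoxide dismutase, by 4.44 ± 0.05, and TNFAIP3 and NFKBIA, feedback inhibitors of NF-κB, by 4.36 ± 0.05 and 2.83 ± 0.06. The NF-κB list passed camera (median 1.86, adjusted p = 1.96e-25, and adjusted p = 0.0898 with an estimated correlation). VCAM1, an adhesion molecule on the fixed panel, was too low to be tested, with 0 and 2 mock counts and 7 and 8 TNF counts.

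All 39 interferon-stimulated genes rose (39 adjusted over the list alone), among them the antiviral genes RSAD2 (6.35 ± 0.24), OAS1 (5.62 ± 0.23) and IFI44L (5.79 ± 0.26). Their median log2 CPM was 3.26 and 3.79 in the mock libraries and 7.12 and 7.48 in the TNF libraries, so libraries of one group differed by 0.526 and 0.362. The list passed camera (median 3.89, adjusted p = 2.01e-28, and adjusted p = 0.229 with an estimated correlation). All 17 genes of MHC class I antigen presentation rose (17 adjusted over the list alone), led by the immunoproteasome subunit PSMB9 (3.40 ± 0.13) and the peptide transporter TAP1 (2.69 ± 0.08), and the list passed camera (median 1.36, adjusted p = 1.75e-17, and adjusted p = 0.146 with an estimated correlation). IDO1, which degrades tryptophan, had 0 and 3 mock counts and was 128 times higher (95% counting interval 43.5 to 624), and TNFSF10, the death ligand TRAIL, was 60.1 times higher (31.4 to 132). Of 21 tested cell death regulators 14 rose and 7 did not pass (14 adjusted over the list alone), including the BH3-only gene PMAIP1 (1.31 ± 0.08) and the inflammatory caspase gene CASP4 (1.02 ± 0.08), and the list passed camera (median 0.39, adjusted p = 3.43e-05, and adjusted p = 0.0898 with an estimated correlation).

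Among 21 tested matrix proteases, 11 rose, 3 fell and 7 did not pass (11 and 5 adjusted over the list alone). CTSS, a lysosomal cysteine protease, rose by 3.54 ± 0.11, and the collagenase MMP1 went from 263 ± 55.7 to 652 ± 7.17 CPM (1.30 ± 0.09). The stromelysin MMP3, the most abundant of the fixed panel of 12 genes, went from 3318 ± 65.6 to 6188 ± 291 CPM (0.90 ± 0.04). The protease list passed camera (median 0.29, adjusted p = 0.00453, and adjusted p = 0.138 with an estimated correlation). Components of the TNF receptor and TAK1 pathway had 10 members higher, 1 lower and 11 not passing of 22 (10 and 1 adjusted over the list alone). TNFRSF1B, the second TNF receptor, rose by 1.12 ± 0.15 and the adaptor TRAF2 by 1.02 ± 0.08, and that list passed camera (median 0.08, adjusted p = 0.0104, and adjusted p = 0.144 with an estimated correlation). Its median was 0.009 with library totals only, with 9 higher and 3 lower, and 0.018 with upper-quartile scaling. Of 13 tested synovial fibroblast markers 8 rose, 1 fell and 4 did not pass (8 and 1 adjusted over the list alone), with HAS2, a hyaluronan synthase, up by 1.89 ± 0.07, podoplanin (PDPN) up by 1.28 ± 0.13 and the growth factor receptor PDGFRB down (−0.60 ± 0.06). That list passed camera (median 0.22, adjusted p = 0.0109, and adjusted p = 0.237 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 0.36 ± 0.09 (adjusted p = 0.00334), and this call was lost without mock replicate 1 (0.24, adjusted p = 0.0550) and without TNF replicate 2 (0.28, adjusted p = 0.0632). The largest decreases were in the urea transporter SLC14A1 (−2.98 ± 0.16), the RNA-binding gene CSDC2 (−2.34 ± 0.21), the keratin KRT18 (−2.33 ± 0.19) and the lipid transporter ABCA8 (−2.08 ± 0.21).

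In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5077 genes differed between TNF and mock, 2857 higher and 2220 lower, and 929 of them changed at least 2-fold, 692 up and 237 down. The same test with library totals only gave 2147 higher and 3474 lower, and with upper-quartile scaling 2234 higher and 3356 lower. DESeq2 called 3301 genes.

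**Figure D1:**
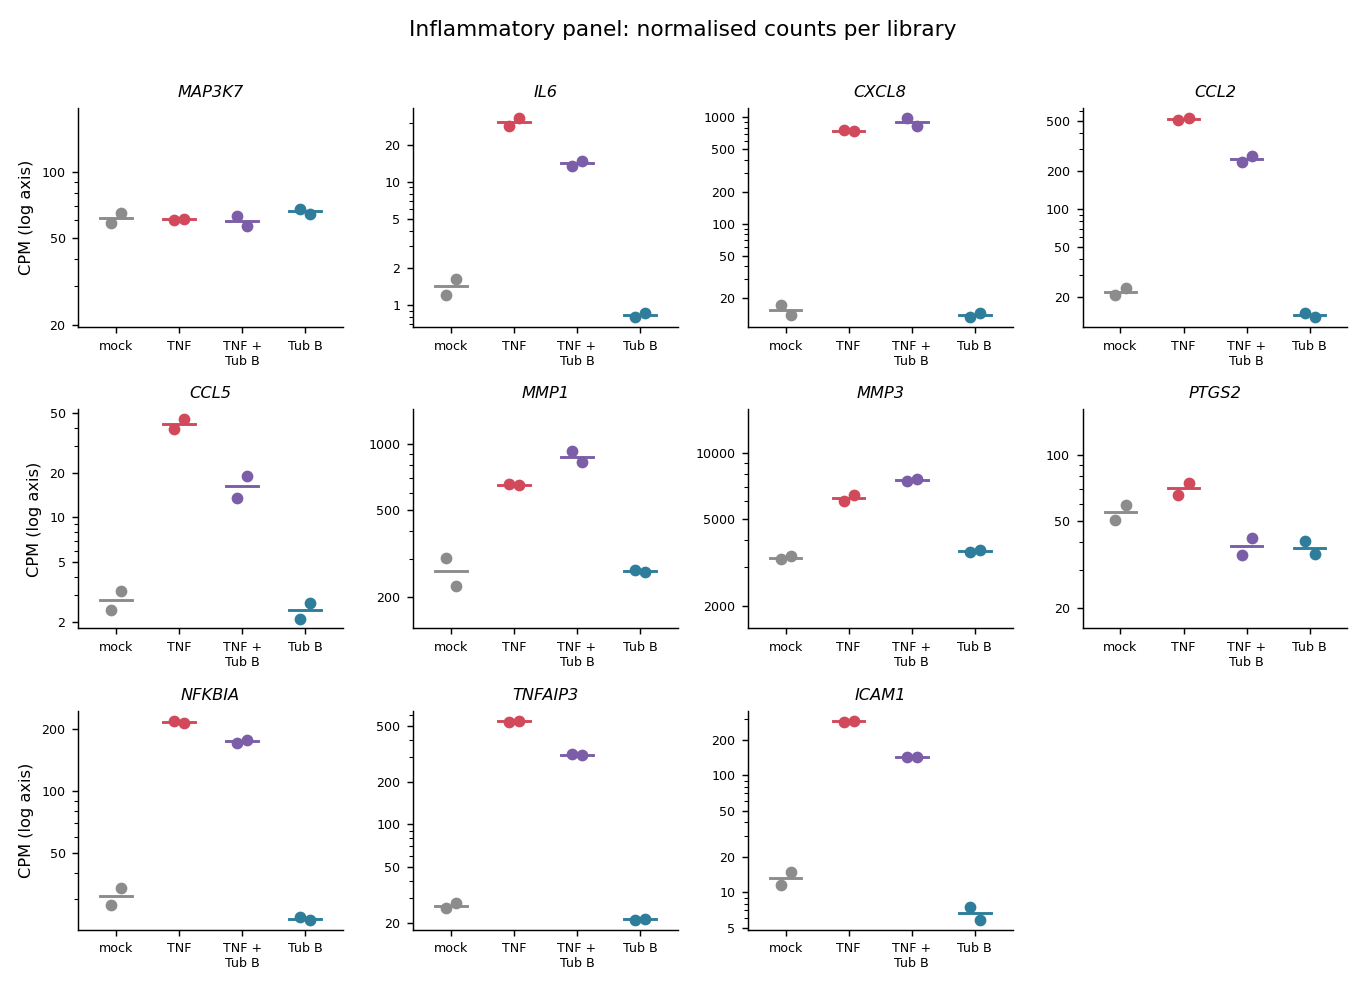
Expression of the 11 tested genes of the fixed panel in every library, in CPM on a log axis of its own for each gene. Each point is 1 library and the horizontal line is the mean of the 2 libraries of a group. IL6, CCL2, CCL5 and ICAM1 were highest in the TNF libraries, while MAP3K7 was at 61.7 ± 4.58 CPM in mock and 59.5 ± 4.33 CPM in TNF + Tub B.

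The comparison of TNF + Tub B with TNF asked how Tub B, given at the same time as TNF, changed stimulated cells. Interferon-stimulated genes, antigen presentation genes and many chemokines fell, while genes of the NRF2 oxidative stress response rose. CXCL10 fell from 175 ± 21.4 to 22.7 ± 6.74 CPM (SD, n = 2), and TNFSF10 fell from 12.2 ± 2.66 to 1.05 ± 0.0892 CPM. NQO1, a quinone reductase and NRF2 target, rose from 92.3 ± 3.68 to 328 ± 11.3 CPM, and SLC7A11, the cystine transporter, from 7.24 ± 0.606 to 68.0 ± 5.61 CPM. MAP3K7 was at 59.5 ± 4.33 CPM, a log2 fold change of −0.02 ± 0.06 (adjusted p = 0.861).

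Of 39 interferon-stimulated genes, 38 fell and 1 did not pass (39 adjusted over the list alone). BST2, which tethers virus particles to the cell surface, changed by −3.41 ± 0.22, IFI44L by −3.11 ± 0.20, OAS1 by −3.03 ± 0.18 and MX1, an antiviral GTPase, by −2.94 ± 0.21. The list's median log2 CPM was 4.75 and 5.30 in TNF + Tub B libraries, which differed from each other by 0.546, against 7.12 and 7.48 in TNF libraries. The list passed camera (median −2.40, adjusted p = 7.42e-26, and adjusted p = 0.229 with an estimated correlation). All 17 antigen presentation genes fell (17 adjusted over the list alone), including PSMB9 (−1.88 ± 0.11) and TAP1 (−1.50 ± 0.07), and the list passed camera (median −0.68, adjusted p = 3.84e-15, and adjusted p = 0.191 with an estimated correlation). Reads of HLA-F (−1.75 ± 0.11) may include reads of similar class I genes, so its value is uncertain.

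Cytokines and chemokines had 16 members lower, 2 higher and 11 not passing of 29 (21 and 2 adjusted over the list alone). CXCL11 changed by −2.97 ± 0.14, the B cell factor TNFSF13B by −2.64 ± 0.22, CCL5 by −1.38 ± 0.12, IL6 by −1.11 ± 0.10 and CCL2 by −1.05 ± 0.05. CXCL8 was higher by 0.28 ± 0.07 (adjusted p = 0.00449), a call lost without TNF + Tub B replicate 1 (0.15, adjusted p = 0.165) and in DESeq2 (adjusted p = 0.115). The cytokine list passed camera (median −0.71, adjusted p = 4.61e-08, and adjusted p = 0.121 with an estimated correlation). NF-κB targets had 21 members lower, 2 higher and 5 not passing of 28 (22 and 2 adjusted over the list alone), with the adaptor TRAF1 (−1.45 ± 0.12), ICAM1 (−1.02 ± 0.06), the transcription factor IRF1 (−1.01 ± 0.08), BIRC3 (−0.92 ± 0.06), TNFAIP3 (−0.79 ± 0.04) and NFKBIA (−0.32 ± 0.06) all lower. That list passed camera (median −0.38, adjusted p = 4.08e-07, and adjusted p = 0.191 with an estimated correlation). PTGS2 fell (−0.88 ± 0.09), while MMP3 rose (0.28 ± 0.04) and MMP1 rose (0.42 ± 0.09, adjusted p = 0.00172, and 0.0713 in DESeq2). VCAM1 had 1 count in each TNF + Tub B library against 7 and 8 with TNF, a ratio of 0.206 (95% counting interval 0.0229 to 0.886). Matrix proteases had 3 members higher and 7 lower of 21 and did not pass camera (adjusted p = 0.752), nor did the TNF receptor and TAK1 pathway components, with 5 lower of 22 (adjusted p = 0.164). Cell death regulators had 8 members lower, 1 higher and 12 not passing of 21 (9 and 2 adjusted over the list alone), with the initiator caspase gene CASP10 lower (−0.80 ± 0.14). That list passed camera (median −0.15, adjusted p = 0.0146, and adjusted p = 0.191 with an estimated correlation), a call lost without TNF + Tub B replicate 2 (adjusted p = 0.0501), and with library totals only its median was −0.03, with 6 members lower and 3 higher.

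Of 22 NRF2 targets, 20 rose and 2 did not pass (20 adjusted over the list alone). HMOX1, the inducible heme oxygenase, rose by 1.45 ± 0.06, TXNRD1, a thioredoxin reductase, by 1.39 ± 0.05 and AKR1C1, an aldo-keto reductase, by 3.06 ± 0.16. AKR1C1 has near-identical copies, so its own share of the reads is uncertain. The list passed camera (median 0.80, adjusted p = 7.17e-19, and adjusted p = 0.121 with an estimated correlation). Of 4 tested targets of the aryl hydrocarbon receptor, 2 rose and 2 did not pass (2 adjusted over the list alone): CYP1B1, a cytochrome P450 enzyme, by 2.27 ± 0.15 and TIPARP, a feedback repressor of that receptor, by 0.70 ± 0.05. This list also passed camera (median 0.98, adjusted p = 0.00203, and adjusted p = 0.254 with an estimated correlation). KYNU, an enzyme of tryptophan breakdown, rose by 1.84 ± 0.16.

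Structural matrix genes fell in 24 of 29 members with 5 not passing (24 adjusted over the list alone), among them elastin (ELN, −1.79 ± 0.11), thrombospondin (THBS1, −0.79 ± 0.07) and tenascin (TNC, −0.73 ± 0.04), and the list passed camera (median −0.35, adjusted p = 1.89e-09, and adjusted p = 0.340 with an estimated correlation). Genes that respond to TGF-β or YAP fell in 15 of 17 members with 2 not passing (15 adjusted over the list alone), including ANKRD1 (−1.69 ± 0.19), CTGF (−1.27 ± 0.08) and the smooth muscle gene CNN1 (−0.90 ± 0.10), and that list passed camera (median −0.41, adjusted p = 9.92e-09, and adjusted p = 0.229 with an estimated correlation). Synovial fibroblast markers had 8 members lower, 1 higher and 4 not passing of 13 (9 and 1 adjusted over the list alone), with HAS2 at −0.76 ± 0.07 and the cadherin CDH11 at −0.48 ± 0.05, and passed camera (median −0.22, adjusted p = 0.00256, and adjusted p = 0.191 with an estimated correlation). WNT pathway genes had 7 lower and 5 not passing of 12 (9 adjusted over the list alone), with the receptor FZD7 at −0.52 ± 0.08, and passed camera (median −0.26, adjusted p = 0.00301, and adjusted p = 0.191 with an estimated correlation). Scaled by library totals only, matrix genes had 17 members lower, 1 higher and a median of −0.23, synovial markers 4 lower, 1 higher and a median of −0.10, and WNT genes 5 lower and a median of −0.14.

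DNA replication and mitosis genes moved apart. Of 25 replication genes 14 rose and 11 did not pass (18 higher and 1 lower adjusted over the list alone), with cyclin genes CCNE2 (0.73 ± 0.14) and CCNE1 (0.59 ± 0.10) highest, and the list passed camera (median 0.26, adjusted p = 2.92e-05, and adjusted p = 0.470 with an estimated correlation). Of 25 mitosis genes 14 fell and 11 did not pass (14 adjusted over the list alone), including the kinesin KIF20A (−0.60 ± 0.05), the anaphase activator CDC20 (−0.56 ± 0.07) and cyclin B1 (CCNB1, −0.50 ± 0.06), and the list passed camera (median −0.17, adjusted p = 0.00318, and adjusted p = 0.518 with an estimated correlation). With library totals only, which moved the median of all genes by 0.115, 21 replication genes were higher, and 1 mitosis gene was higher and 6 lower around a median of −0.05. Neither list passed with fry (adjusted p = 0.0920 for replication and 0.0563 for mitosis genes).

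In edgeR, 3367 genes differed between TNF + Tub B and TNF, 1184 higher and 2183 lower, and 440 changed at least 2-fold, 62 up and 378 down. The split was 3431 higher and 1325 lower with library totals only and 1733 higher and 1781 lower with upper-quartile scaling, so the balance of small changes followed the scaling. The count was 2165 without TNF replicate 1, 2129 without TNF replicate 2, 2024 without TNF + Tub B replicate 1 and 1950 in DESeq2.

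To see what Tub B did without TNF, Tub B libraries were compared with mock libraries. Most NRF2 targets and aryl hydrocarbon receptor targets rose, and 21 of 39 interferon-stimulated genes, 17 of 25 mitosis genes and 10 of 17 TGF-β or YAP responsive genes fell. CYP1B1 rose from 1.16 ± 0.188 to 11.9 ± 0.861 CPM (SD, n = 2), SLC7A11 from 9.33 ± 0.0308 to 88.6 ± 16.9 CPM and NQO1 from 91.1 ± 3.17 to 460 ± 32.4 CPM. KRT18 fell from 17.5 ± 3.43 to 5.05 ± 1.63 CPM, and HAS2 fell as well (−1.66 ± 0.10). MAP3K7 was at 65.9 ± 2.11 CPM, a log2 fold change of 0.10 ± 0.06 against mock (adjusted p = 0.327).

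Of 22 NRF2 targets, 20 rose and 2 did not pass (22 adjusted over the list alone), with HMOX1 (1.88 ± 0.06), TXNRD1 (1.53 ± 0.05) and AKR1C1 (2.74 ± 0.17) among the largest, and the list passed camera (median 0.90, adjusted p = 1.25e-24, and adjusted p = 0.145 with an estimated correlation). PIR, another gene induced by oxidative stress, rose by 1.72 ± 0.18. Aryl hydrocarbon receptor targets rose in 3 of 4 members with 1 not passing (4 adjusted over the list alone), CYP1B1 by 3.38 ± 0.18 and TIPARP by 0.90 ± 0.05, and passed camera (median 1.45, adjusted p = 1.96e-05, and adjusted p = 0.302 with an estimated correlation). Interferon-stimulated genes fell in 21 of 39 members with 18 not passing (25 adjusted over the list alone), from a median log2 CPM of 3.26 and 3.79 in mock, which differed by 0.526, to 2.42 and 2.63 in Tub B. MX1 changed by −2.14 ± 0.39 (adjusted p = 0.00122), IFIT1 by −1.60 ± 0.25 and OAS3 by −1.39 ± 0.20, and the list passed camera (median −0.82, adjusted p = 4.47e-12, and adjusted p = 0.454 with an estimated correlation). OAS2 fell (−1.50 ± 0.33), but lost its call without Tub B replicate 1 (adjusted p = 0.0719) and without Tub B replicate 2 (adjusted p = 0.0780). Antigen presentation genes had 2 members lower and 15 not passing of 17 (2 adjusted over the list alone), with PSME2 at −0.33 ± 0.05, and passed camera (median −0.14, adjusted p = 0.00147, and adjusted p = 0.551 with an estimated correlation), a call lost without mock replicate 2 (adjusted p = 0.0587), and their median was −0.08 with library totals only.

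Cytokines and chemokines had 7 members lower and 22 not passing of 29 (9 adjusted over the list alone), with CCL2 (−0.61 ± 0.09) and CXCL12 (−0.60 ± 0.05) lower. Their median was −0.28, and −0.43 without mock replicate 1. It was −0.19 with the 2 members of 3 or fewer counts at their bound, or at 0 where the interval included no change. That list passed camera (adjusted p = 0.000640, and adjusted p = 0.182 with an estimated correlation). IL6 (−0.73 ± 0.30, adjusted p = 0.133), CXCL8 (−0.19 ± 0.11, adjusted p = 0.331) and CCL5 (−0.19 ± 0.26, adjusted p = 0.716) did not pass, and neither did MMP3 (0.10 ± 0.04, adjusted p = 0.115). MMP1 stood at −0.01 ± 0.09 (adjusted p = 0.973), and took opposite signs without mock replicate 1 (0.23, adjusted p = 0.0129) and without mock replicate 2 (−0.20, adjusted p = 0.0155). NF-κB targets had 8 members lower, 2 higher and 18 not passing of 28 (8 and 3 adjusted over the list alone), with ICAM1 (−0.94 ± 0.13), RELB (−0.58 ± 0.11) and TNFAIP3 (−0.32 ± 0.06) lower. The NF-κB list was at the edge of the threshold (median −0.07, adjusted p = 0.0479, and adjusted p = 0.551 with an estimated correlation), and its median was −0.11 without mock replicate 1, −0.04 without mock replicate 2 and −0.01 with library totals only. Its call was lost without mock replicate 2 (adjusted p = 0.420), TNF replicates 1 and 2 (0.0593 and 0.0590), TNF + Tub B replicates 1 and 2 (0.0695 and 0.0692) and Tub B replicate 2 (0.0955), and with fry (0.0945). PTGS2 fell (−0.52 ± 0.09), a call lost without Tub B replicate 2 (−0.43, adjusted p = 0.0523).

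Mitosis genes fell in 17 of 25 members with 8 not passing (22 adjusted over the list alone), including CDC20 (−0.68 ± 0.07), the mitotic kinase PLK1 (−0.59 ± 0.07) and the proliferation antigen MKI67 (−0.47 ± 0.06). The mitosis list passed camera (median −0.38, adjusted p = 4.47e-12, and adjusted p = 0.389 with an estimated correlation), and its median was −0.24 without mock replicate 1. DNA replication genes fell in 8 of 25 members with 17 not passing (11 adjusted over the list alone), MCM7, a subunit of the replicative helicase, by −0.61 ± 0.07. That list passed camera (median −0.22, adjusted p = 0.000629, and adjusted p = 0.595 with an estimated correlation), a call lost without mock replicate 1 (median −0.03, adjusted p = 0.299), and its median was −0.33 without mock replicate 2. TGF-β or YAP responsive genes fell in 10 of 17 members with 7 not passing (14 adjusted over the list alone), with CNN1 (−0.84 ± 0.09), CTGF (−0.58 ± 0.07) and the tropomyosin TPM1 (−0.55 ± 0.07) lower, and passed camera (median −0.26, adjusted p = 3.34e-07, and adjusted p = 0.436 with an estimated correlation). Structural matrix genes had 9 members lower, 2 higher and 18 not passing of 29 (10 and 2 adjusted over the list alone), with ELN (−0.91 ± 0.10), TNC (−0.52 ± 0.04) and versican (VCAN, −0.46 ± 0.05) lower. The matrix list passed camera (median −0.11, adjusted p = 0.00147, and adjusted p = 0.671 with an estimated correlation), a call lost without mock replicate 2 (median −0.04, adjusted p = 0.421), while its median was −0.22 without mock replicate 1 and −0.05 with library totals only. With fry the Tub B calls of interferon-stimulated genes (adjusted p = 0.0817), antigen presentation, replication (0.224) and matrix genes (0.193) were lost.

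In edgeR, 2120 genes differed between Tub B and mock, 804 higher and 1316 lower, and 113 changed at least 2-fold, 49 up and 64 down. With library totals only the split was 1530 higher and 867 lower. The count was 1263 without Tub B replicate 1, 715 without Tub B replicate 2 and 1264 in DESeq2.

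**Figure D2:**
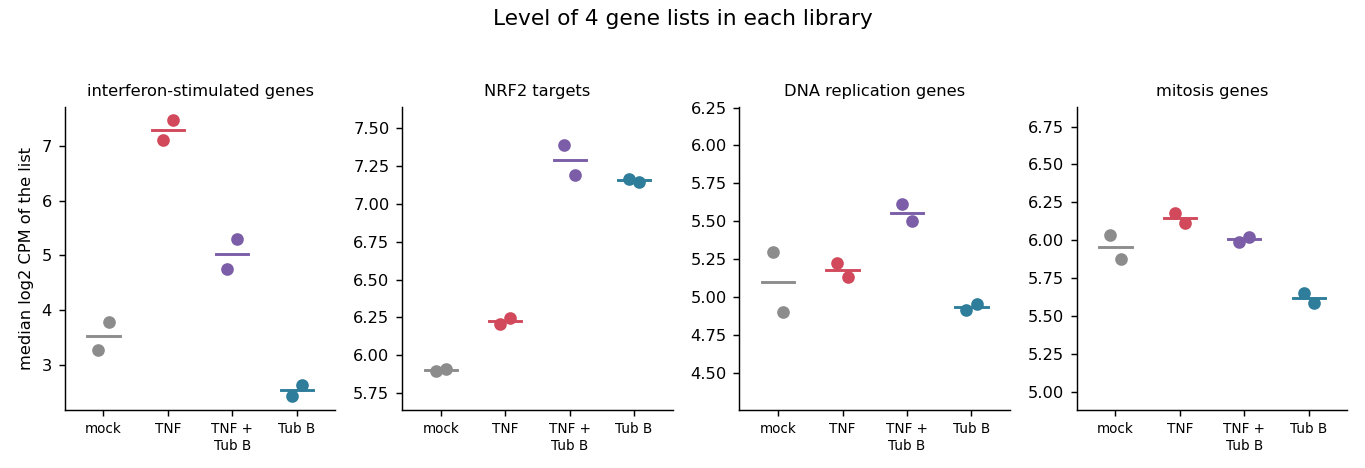
Median log2 CPM (vertical axis) of the interferon-stimulated, NRF2, DNA replication and mitosis lists in each of the 8 libraries, with a line at the group mean. Interferon-stimulated genes were at 7.12 and 7.48 in TNF libraries and 4.75 and 5.30 in TNF + Tub B libraries, and NRF2 targets at 5.89 and 5.91 in mock and 7.16 and 7.15 in Tub B libraries.

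To ask whether cells still responded to TNF when Tub B was present, TNF + Tub B was compared with Tub B, a pair of groups that shares no library with TNF against mock. TNF still raised cytokines in 26 of 29 members, with 1 lower and 2 not passing (26 and 1 adjusted over the list alone), and the list passed camera with the preset (adjusted p = 2.31e-20) and with an estimated correlation (adjusted p = 0.0181). Its median was 3.45, or 3.32 with members of 3 or fewer counts at their bound. NF-κB targets rose in 24 of 28 members with 4 not passing (26 adjusted over the list alone), with a median of 1.67, or 1.53 with the low member at its bound (adjusted p = 1.99e-23, and adjusted p = 0.103 with an estimated correlation). All 39 interferon-stimulated genes rose (39 adjusted over the list alone, median 2.32, adjusted p = 5.19e-22, and adjusted p = 0.294 with an estimated correlation), as did all 17 antigen presentation genes (17 adjusted over the list alone, median 0.72, adjusted p = 5.87e-13, and adjusted p = 0.229 with an estimated correlation). DNA replication genes rose in 24 of 25 members with 1 not passing (24 adjusted over the list alone, median 0.66, adjusted p = 6.67e-12, and adjusted p = 0.351 with an estimated correlation), and mitosis genes in 19 of 25 with 6 not passing (19 adjusted over the list alone, median 0.37, adjusted p = 5.56e-08, and adjusted p = 0.368 with an estimated correlation). In TNF against mock, 9 of 25 replication genes had risen with 16 not passing (10 adjusted over the list alone, median 0.16, adjusted p = 0.0142, and adjusted p = 0.690 with an estimated correlation). That replication call was lost without mock replicate 2 (median 0.04, adjusted p = 0.481), without TNF replicate 1 (adjusted p = 0.0814) and with fry (adjusted p = 0.221), and its median was 0.33 without mock replicate 1. It had, with library totals only, 4 members higher, 1 lower and a median of 0.09. Structural matrix genes fell in 18 of 29 members, with 5 higher and 6 not passing (18 and 5 adjusted over the list alone, median −0.28, adjusted p = 0.000546, and adjusted p = 0.602 with an estimated correlation).

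Across the 5077 genes called in TNF against mock, the slope of the response with Tub B on the response without it was 0.709, where a simulated equal response gave 0.912 (0.898 to 0.926 in 20 simulations). The median change in the direction of TNF was 0.303 with Tub B and 0.412 alone, where a simulated equal response gave 0.382 and 0.439. The response was smaller with Tub B for 72.2% of these genes, against 62.5% in the simulation. It kept its direction for 4680 of them, and 2968 were also called in that direction. A simulated equal response gave, on average, 5847 and 4216 of 5985 genes called. The simulations took the fitted group levels as the true ones, noise included, and called more genes than the 5077 observed. They thus understate how far called genes shrink in a second estimate, and part of each gap to the simulated values may come from this. In all, edgeR called 4397 genes between TNF + Tub B and Tub B, 2388 higher and 2009 lower, and 704 at least 2-fold, 473 up and 231 down. With upper-quartile scaling the split was 2018 higher and 2618 lower.

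**Figure D3:**
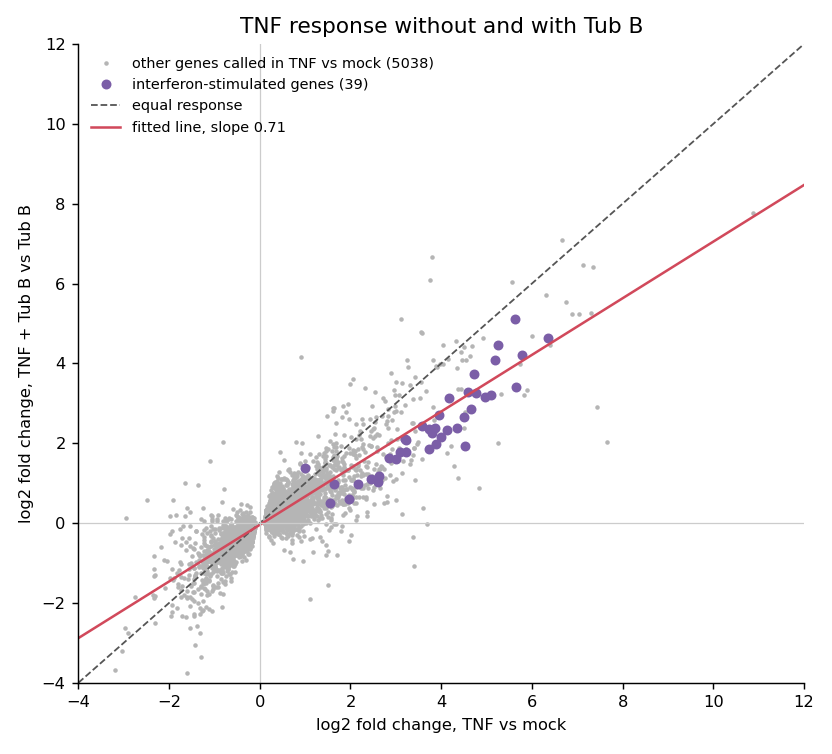
Response to TNF of the 5077 genes called in TNF against mock, as the log2 fold change of TNF against mock (horizontal axis) and of TNF + Tub B against Tub B (vertical axis). The 39 interferon-stimulated genes are purple and the others grey, the dashed line marks equal responses, and the red line is the fit with a slope of 0.71. All but 1 of the purple points lie below the dashed line, with list medians of 3.89 without and 2.32 with Tub B.

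Genes moved by TNF were next asked how Tub B moved them in TNF-treated cells. Of the 2857 genes that TNF raised, 1196 (41.9%) were called lower and 148 higher in TNF + Tub B, where independent lists would give 375 and 203. Of the 2220 genes that TNF lowered, 380 (17.1%) were called higher and 314 lower, against 158 and 291 for independent lists. Among genes raised at least 2-fold, 415 of 692 (60.0%) were called back toward mock and 21 (3.03%) further from it, and among genes lowered at least 2-fold, 18 of 237 (7.59%) back and 34 (14.3%) further. Chemokines such as CXCL10 and interferon-stimulated genes such as OAS1 were in the first set. Both comparisons use the TNF libraries. With 1 TNF library against mock and the other against TNF + Tub B, a split chosen after seeing the data, the 1576 opposite calls became 971 and 974 and the 462 alike 288 and 240. In both splits, genes raised by TNF were still called back toward mock more often than further from it. Genes lowered by TNF were instead called further more often than back, so the balance of their raw counts was not kept. Relative to independent lists, however, their calls back were still in larger excess than their calls further in both splits. Simulations with no effect of Tub B in TNF-treated cells gave 1.65 opposite calls on average and 5 at most. They gave 1.30 alike calls and 6 at most, so they do not set opposite calls apart from alike ones. The 1576 opposite calls became 1070 without TNF replicate 1, 1009 without TNF replicate 2 and 1066 without TNF + Tub B replicate 1. Calls of the same direction became 217, 267 and 292 in those fits. DESeq2 gave 925 opposite and 276 alike calls. These calls were not counted with library totals only or upper-quartile scaling, which changed the split of higher and lower calls in both comparisons.

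The Tub B responses with and without TNF shared no library. Of the genes called in either, 367 were higher in both (57.2 for independent lists) and 806 lower in both (173 for independent lists), and 31 were called in opposite directions. NQO1, SLC7A11, CYP1B1 and HMOX1 were higher in both, and ICAM1, CCL2, ELN and CDC20 lower in both. Across all 16647 genes the log2 fold changes correlated with r = 0.404, where genes are not independent replicates. The 1173 shared genes became 525 without Tub B replicate 2 and 741 in DESeq2, and r became 0.253 without mock replicate 2, 0.600 in DESeq2 and 0.0184 without a filter.

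Whether Tub B acted differently with TNF was tested as the interaction, the change with Tub B under TNF minus the change without it. In edgeR 705 genes passed, 173 with a more positive and 532 with a more negative effect of Tub B under TNF, and 140 differed at least 2-fold, 18 up and 122 down. With library totals only the split was 291 and 379. Interferon-stimulated genes had 25 members more negative and 14 not passing of 39 (33 adjusted over the list alone, median −1.40, adjusted p = 1e-19, and adjusted p = 0.404 with an estimated correlation), with SAMD9L, an antiviral gene, at −1.91 ± 0.30. Antigen presentation genes had 15 more negative and 2 not passing of 17 (16 adjusted over the list alone, median −0.56, adjusted p = 2.95e-16, and adjusted p = 0.404 with an estimated correlation), with TAP1 at −1.30 ± 0.11 and the immunoproteasome subunit PSMB8 at −1.01 ± 0.10. NF-κB targets had 5 more negative, 1 more positive and 22 not passing of 28 (12 and 1 adjusted over the list alone, median −0.24, adjusted p = 0.000148, and adjusted p = 0.404 with an estimated correlation), with IRF1 at −1.18 ± 0.14 and TRAF1 at −1.76 ± 0.27. Cytokines had 6 more negative, 1 more positive and 22 not passing of 29 (7 and 2 adjusted over the list alone, median −0.28, adjusted p = 0.000689, and adjusted p = 0.404 with an estimated correlation), with a median of −0.45 without TNF + Tub B replicate 2. Cytokines with a more negative effect included TNFSF13B (−3.25 ± 0.51) and the macrophage growth factor CSF1 (−0.93 ± 0.09). Structural matrix genes had 14 more negative and 15 not passing of 29 (19 more negative and 1 more positive adjusted over the list alone, median −0.23, adjusted p = 7.19e-06, and adjusted p = 0.526 with an estimated correlation). DNA replication genes had 16 more positive and 9 not passing of 25 (22 adjusted over the list alone, median 0.51, adjusted p = 1.85e-13, and adjusted p = 0.404 with an estimated correlation), and their median was 0.31 without mock replicate 1. With fry, cytokines and antigen presentation genes passed, while interferon-stimulated genes, NF-κB targets and replication genes (adjusted p = 0.0879 for each) and matrix genes (0.158) did not. For IL6 (−0.38 ± 0.34, adjusted p = 0.649), ICAM1 (−0.08 ± 0.14, adjusted p = 0.841) and NFKBIA (0.03 ± 0.09, adjusted p = 0.931) the interaction did not pass. The count of 705 became 457 without mock replicate 1, 1328 without mock replicate 2, 324 without TNF replicate 2, 316 without TNF + Tub B replicate 1, 306 and 381 without Tub B replicates 1 and 2, and 420 in DESeq2.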

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

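The comparisons with matched genes, between single libraries of TNF and TNF + Tub B and with IFNB1 counts, the test without gene copies, the reading of solvent labels and the comparison of replication with mitosis were chosen only after the results were seen. The items here differed between groups: the effect of Tub B with TNF differed from its effect without TNF in the interaction test. In all, 705 genes did so.

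Interferon-stimulated genes had the most negative interaction median of the lists (−1.40, a call lost with fry at adjusted p = 0.0879) and fell further than other TNF-raised genes in TNF + Tub B. Their median lay 1.46 below that of genes matched on the TNF change (difference −1.46, SD 0.37 over pairings of single libraries). The matched genes fell as well (median −0.94), so strong TNF responses returned in part whatever their list. The difference argues only against such a return as the whole of the fall in interferon-stimulated genes. The median of the interferon-stimulated genes was −2.40 at equal depth. Thinning draws reads at random and leaves scaled changes much as they were, so it could not have pointed to depth. Drift between cultures cannot be told apart: the lowest TNF library stood 1.82 log2 units above the highest TNF + Tub B library, but the labels do not say that the libraries of a group are separate cultures, so their spread sets no bound on it. A smaller rise of the interferon-β gene IFNB1 cannot be told apart either, as its ratio of 0.407 has an interval of 0.119 to 1.13 on 14 and 5 counts with TNF and 3 and 2 with both.

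With Tub B, 20 of 22 NRF2 targets were higher both with and without TNF, as were 2 of 4 aryl hydrocarbon receptor targets with TNF and 3 without, no list call held with an estimated correlation (adjusted p from 0.121 to 0.302), and the interaction medians were −0.11 and −0.49. Without the 6 NRF2 list members that have near-identical copies, the median in Tub B against mock was 0.84, against 0.90 for all 22. The rise of the NRF2 list thus did not rest on those members. Receptor targets were not part of this comparison. The labels name DMSO for 0 libraries with Tub B and for 2 mock libraries, so an effect of solvent cannot be told apart, since the solvent in the Tub B libraries is not stated. The interaction call of the NRF2 list was lost without mock replicate 2 (adjusted p = 0.184), TNF replicates 1 and 2 (0.119 and 0.0544), TNF + Tub B replicate 2 (0.256) and Tub B replicate 2 (0.322), with a prior count of 0.5 (0.0530) and with fry (0.209), and that of the receptor targets without mock replicate 1 (0.0855), TNF replicate 2 (0.0544), TNF + Tub B replicates 1 and 2 (0.0501 and 0.0598) and Tub B replicate 2 (0.0688), and with fry (0.0879). Their medians were −0.19 without TNF + Tub B replicate 1 for NRF2 targets, and −0.18 and −0.76 without mock replicates 1 and 2 for receptor targets.

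In TNF + Tub B against TNF, 14 of 25 replication genes were higher and 14 of 25 mitosis genes lower, but both list calls were lost with fry (adjusted p = 0.0920 and 0.0563) and with an estimated correlation (0.470 and 0.518), and the interaction medians were 0.51 and 0.17. The medians of the lists differed by 0.43 (SD 0.06 over pairings of single libraries). This difference restates the opposite directions for which the lists were picked out. It is therefore no separate test of an overall change in how many cells divide. The lowest difference without 1 library was 0.35, which argues against a single library. The difference at equal depth was 0.41, but random thinning leaves scaled changes much as they were and could not test depth. Part of the interaction rests on the mock libraries, as the replication median was 0.31 without mock replicate 1 and the mitosis median 0.06 without mock replicate 1 and 0.27 without mock replicate 2. Drift between cultures and the phase of the cells were not tested, as the labels name neither separate cultures nor a cell cycle measurement.

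Of the other lists, the interaction median was −0.24 for NF-κB targets, −0.28 for cytokines (−0.45 without TNF + Tub B replicate 2), −0.23 for structural matrix genes, −0.56 for antigen presentation and −0.17 for cholesterol genes. Smaller medians were 0.10 for p53 targets, −0.11 for ER chaperones, −0.12 for TGF-β or YAP responsive genes, 0.11 for mitochondrially encoded genes and 0.064 for ribosomal protein genes, and each of these 5 calls was lost without at least 1 library. The p53 call was lost without mock replicate 2 (adjusted p = 0.0552), the ribosomal call without TNF replicate 2 (0.0563), and the mitochondrial call without TNF + Tub B replicate 2 (0.0549) and Tub B replicate 1 (0.132). ER chaperones lost theirs without mock replicate 1 (0.151), TNF replicate 2 (0.111), TNF + Tub B replicate 1 (0.0941) and Tub B replicate 2 (0.0732). TGF-β or YAP genes lost theirs without mock replicate 1 (0.166), TNF replicate 2 (0.0516), TNF + Tub B replicates 1 and 2 (0.0501 and 0.0590) and Tub B replicate 1 (0.127). Their medians moved most without mock replicate 1 for TGF-β or YAP genes (−0.05, and −0.23 without mock replicate 2) and ER chaperones (−0.06), without TNF replicate 1 (0.089) and Tub B replicate 1 (0.039) for ribosomal genes, and without Tub B replicates 1 and 2 for mitochondrial genes (0.07 and 0.17). Scaled by library totals only, the median was 0.16 for p53 targets, −0.05 for ER chaperones and for NRF2 targets, −0.06 for TGF-β or YAP genes, −0.10 for cholesterol genes, 0.17 for mitochondrial genes and 0.13 for ribosomal genes. None of the 15 lists kept its interaction call with an estimated correlation, and only cytokines and antigen presentation genes did with fry.

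Among single genes, the epidermal envelope gene LCE3D had an interaction of 1.99 (1.27 without mock replicate 1), LCE2A 1.66 (0.98 without mock replicate 1), LZTS1 1.37 and the replication gene FAM111B 1.35 (0.86 without mock replicate 1). The cell cycle factors E2F8 at 1.48 and E2F2 at 1.16 were 0.91 (adjusted p = 0.201) and 0.65 (adjusted p = 0.436) without mock replicate 1. E2F8 also lost its call without TNF replicate 2 (0.0642), TNF + Tub B replicate 1 (0.130) and Tub B replicates 1 and 2 (0.119 and 0.0801), and E2F2 without any library except mock replicate 2. LCE2A and LZTS1 lost theirs without Tub B replicate 1 (adjusted p = 0.0541 and 0.0540). On the negative side, TNFSF13B was at −3.25, BATF2 at −2.84, ISG20 at −2.57, ODF3B at −2.42, GMPR at −2.26, CMPK2 at −2.22, CCL5 at −1.20, TNFAIP3 at −0.47 and CCL2 at −0.44. ISG20 lost its call without Tub B replicate 2 (adjusted p = 0.0885), CMPK2 without either Tub B replicate (0.0822 and 0.227), and CCL2 and CCL5 each without mock replicate 1 (0.130 and 0.159), TNF replicate 2 (0.0813 and 0.0666), TNF + Tub B replicate 1 (0.0859 and 0.0777), Tub B replicate 1 (0.172 and 0.0924) and Tub B replicate 2 (0.0553 and 0.242).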

How the results depend on the processing

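Thinning to equal depth and splitting the TNF libraries were the alternatives chosen after the results were seen. Of 298 results for named genes, 228 kept their direction and side of the threshold in all 10 other settings and all 8 fits without 1 library, 64 lost a call in at least 1, 6 gained one and 1 reversed. The 1 that reversed, MMP1, had not been called with the main settings. No gene called with the main settings was called in the other direction in another setting. DESeq2 called 3301 genes in TNF against mock, 1950 in TNF + Tub B against TNF, 1264 in Tub B against mock and 420 in the interaction, and gave a median TNF response with Tub B of 0.370, 925 opposite and 276 alike calls, 741 shared Tub B genes and a correlation of 0.600. The cause was not tested. Without a filter, which adds genes with few counts, the slope was 0.648, the median 0.333 and the correlation 0.0184. At least 2-fold changes numbered 929, 440, 113, 704 and 140 in the 5 contrasts, with a median of 1.09, 248 opposite, 24 alike and 52 shared genes. An adjusted p below 0.01 left 2106 genes in TNF + Tub B against TNF, 1058 in Tub B against mock and 326 in the interaction. With an estimated correlation 1, 0, 0, 1 and 0 lists passed in place of 16, 20, 16, 17 and 15, and the cause was not tested. With fry, which tests each list alone, 25 passed in TNF against mock, 21 in TNF + Tub B against TNF, 26 in TNF + Tub B against Tub B and 3 in the interaction. Of the lists passing camera, fry kept 15 of 16 in TNF against mock (not replication), 16 of 20 in TNF + Tub B against TNF (not replication, mitosis, mitochondrial or ribosomal genes) and 2 of 15 in the interaction (cytokines and antigen presentation). Fry gave the opposite direction for protease inhibitors (adjusted p = 0.00400) and heat shock genes (0.0143) in TNF against mock and for protease inhibitors in TNF + Tub B against Tub B (0.00616). In Tub B against mock, 10 of the 16 lists were also called by fry, not interferon-stimulated genes (0.0817), NF-κB targets (0.0945), epithelial markers (0.0723), structural matrix (0.193), antigen presentation or replication genes (0.224). A prior count of 0.5 changed 2 list calls, NRF2 targets in the interaction and lysosome genes in Tub B against mock (0.0483). The labels do not say that replicate numbers mark a shared culture or day, and deviations of same-numbered libraries correlated at 0.234 (mock and TNF), 0.237 (mock and TNF + Tub B) and 0.171 (TNF and TNF + Tub B), but at −0.119, 0.0118 and 0.0883 for these groups with Tub B, so the numbers were not taken as pairs. With a replicate block 5368, 3656, 2492, 4671 and 914 genes were called in the 5 contrasts in place of 5077, 3367, 2120, 4397 and 705, the median TNF response was 0.289, and of the list calls only NF-κB targets (0.0639) and epithelial markers (0.0609) in Tub B against mock and NRF2 targets in the interaction (0.0558) fell on the other side of the threshold. With the TNF libraries split, opposite calls were 971 and 974 and alike calls 288 and 240, with fewer libraries per contrast. Without 1 library, counts ranged from 2024 (without TNF + Tub B replicate 1) to 3798 in TNF + Tub B against TNF, from 715 (without Tub B replicate 2) to 2130 in Tub B against mock and from 306 (without Tub B replicate 1) to 1328 (without mock replicate 2) in the interaction. In those fits the slope was 0.618 to 0.730, the median 0.294 to 0.382, opposite calls 1009 to 1683, alike calls 217 to 568, shared genes 525 to 1087 and the correlation 0.253 to 0.353. MMP1 in Tub B against mock went from −0.20 without mock replicate 2 to 0.23 without mock replicate 1. Its level was 303 CPM in mock replicate 1 and 224 CPM in mock replicate 2. Tub B replicates 1 and 2, at 265 and 261 CPM, lay between them, so the sign followed which mock library was kept. At equal depth 4309, 2986, 1758, 4112 and 594 genes were called, of 15688 tested in place of 16647. Thinning removes reads from all but the smallest library, which by itself leaves fewer counts to pass the filter and the tests.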

Other observations

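The list tests in this part were all fixed before the results were seen. Hypoxia and glycolysis genes rose with TNF in 19 of 23 members, with 1 lower (median 0.39, adjusted p = 1.56e-06, and adjusted p = 0.138 with an estimated correlation), and in TNF + Tub B against TNF 16 rose (median 0.19, adjusted p = 5.91e-07, and adjusted p = 0.191 with an estimated correlation). In Tub B against mock 8 rose (median 0.23, adjusted p = 2.25e-06, and adjusted p = 0.247 with an estimated correlation), and the median was 0.14 without mock replicate 1. Scaled by library totals only, 18 rose in TNF + Tub B against TNF (median 0.31) and 15 in Tub B against mock (median 0.28). ER chaperones rose with TNF in 14 of 19 members (median 0.19, adjusted p = 5.07e-05, and adjusted p = 0.281 with an estimated correlation) and fell in 10 in TNF + Tub B against TNF (median −0.17, adjusted p = 3.27e-05, and adjusted p = 0.254 with an estimated correlation). Scaled by library totals only, 7 rose with TNF (median 0.11) and 4 fell in TNF + Tub B against TNF (median −0.05). Metallothioneins, which bind metals and whose copies may share reads, rose with TNF in 7 of 8 members (median 0.94, adjusted p = 0.000117, and adjusted p = 0.109 with an estimated correlation), fell in 6 in TNF + Tub B against TNF (median −0.85, adjusted p = 5.31e-05, and adjusted p = 0.130 with an estimated correlation) and fell in 4 in Tub B against mock (median −0.55, adjusted p = 0.000204, and adjusted p = 0.182 with an estimated correlation). Ribosomal protein genes fell slightly with TNF in 36 of 53 members (median −0.15, adjusted p = 3.45e-09, and adjusted p = 0.281 with an estimated correlation). Mitosis genes rose with TNF in 13 of 25 members (median 0.21, adjusted p = 0.000780, and adjusted p = 0.598 with an estimated correlation), with a median of 0.13 without mock replicate 2 and 0.32 without mock replicate 1, and 7 rose with library totals only (median 0.14). In poly(A) RNA, replication-dependent histone genes rose with TNF in 6 of 16 members (median 0.35, adjusted p = 0.00364, and adjusted p = 0.138 with an estimated correlation). Histone transcripts without a poly(A) tail were not measured. Mitochondrially encoded genes fell with TNF in 6 of 13 (median −0.12, adjusted p = 0.0109, and adjusted p = 0.598 with an estimated correlation), and in 10 with library totals only (median −0.19).

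Cholesterol genes rose with Tub B alone in 6 of 22 members, with 1 lower (median 0.09, adjusted p = 0.0159, and adjusted p = 0.449 with an estimated correlation), a call lost without mock replicate 1 (adjusted p = 0.0687) and without Tub B replicate 1 (adjusted p = 0.102), and 9 rose with library totals only (median 0.14). AP-1 responsive genes fell in 8 of 22 members, with 1 higher (median −0.17, adjusted p = 0.0102, and adjusted p = 0.449 with an estimated correlation), a call lost without Tub B replicate 2 (adjusted p = 0.0521). Targets of p53 rose in 8 of 22 members, with 2 lower, in TNF + Tub B against TNF (median 0.09, adjusted p = 0.0202, and adjusted p = 0.309 with an estimated correlation), a call lost without TNF replicate 2 (adjusted p = 0.0753), and the median was 0.15 without TNF replicate 1 and 0.21 with library totals only, when 12 rose. Epithelial markers fell with Tub B alone in 2 of 6 members, the keratins KRT18 and KRT19 (median −0.46, adjusted p = 0.0232, and adjusted p = 0.452 with an estimated correlation), a call lost without Tub B replicate 2 (adjusted p = 0.0521) and with fry (adjusted p = 0.0723).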
